A study of Mus musculus with 6 samples.

How the data were processed

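Libraries were made from ILCPs sorted as lineage-negative, Flt3−, IL7Rα+, α4β7+, CD90+ and CD25− cells into GFP+ and GFP− fractions, 3 libraries of each, per the labels. Per the labels' protocols, total RNA was turned into cDNA, amplified by single primer isothermal amplification with the Trio RNA-seq kit, depleted of ribosomal RNA and sequenced as paired-end reads on an Illumina NextSeq 500. Such amplification from little RNA can leave transcripts of low level uncounted and can raise the spread between libraries. The labels do not say whether the protocol keeps strand, so overlapping and antisense genes are uncertain.

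The deposited table holds estimated counts per gene for 16383 genes, which are not whole numbers and differ in total between libraries. The submitters' processing notes name Trimmomatic, Bowtie2, kallisto and DESeq2 and the build GRCm38, without versions or roles. The authors' deposited table also gives, per the file headers, log2 fold changes with their errors, a Wald statistic as a score, and p-values and adjusted p-values, and a mean per gene. The deposited mean equals the mean of the rounded estimated counts divided by 1 factor per library, with 0 genes off by more than 1e-06. The estimated counts are therefore not normalized between libraries. Symbols that sort after Trappc10 are not analysed here, among them Zbtb16, and Id1 is not analysed here either. There were 21 symbols read as dates, which stayed in the tests and are not named.

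Libraries were matched to groups and replicate numbers by the labels. Same-numbered GFP+ and GFP− libraries came from the same pooled mice, per the labels, so the numbers pair the samples. As a check, correlations of their deviations from the group means were 0.161, −0.121 and −0.131 for replicates 1, 2 and 3. The pairing therefore rests on the labels.

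Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood test, robust, TMM scaling, filterByExpr) in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment at 0.05. DESeq2 1.42.0 with default settings was run beside it. Other alternatives were the replicate number as a block, scaling by DESeq2's factors or by totals, no filter, a filter at a mean of 50 counts, looser and stricter thresholds, and each replicate and library left out. Alternatives for the DESeq2 calls, camera without single libraries, and limma 3.58.1 with sample weights were chosen after seeing the data. CPM were computed from rounded counts with TMM scaling, and fold changes are GFP+ over GFP−. Where a group had 0 counts in all libraries, the fold is a bound against a floor of 3 counts over the group. The floor covers counting error only, since reads carried no molecular identifiers. Bootstrap intervals (10000 draws) and exact intervals are over genes and leave out the spread between libraries. An adjusted p that DESeq2 left empty stayed empty.

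The tests, the 26 gene lists with 502 members, 438 of them in the table, and the rule for naming genes were fixed before the data were examined. To these came 2 lists by symbol, ribosomal protein genes and mitochondrially encoded genes. The lists are those named in the results, and 26 of the 28 had at least 5 tested members and entered camera, with a preset correlation of 0.01 on log2 CPM with a prior count of 2. Camera with an estimated correlation and fry were run beside it. The naming rule took the 12 largest rises and falls among calls with a mean of at least 20 counts and 1 sign in the 3 pairs, without predicted genes. It also took up to 4 called members of each list, a fixed set of genes whatever their p, and the 2 members of highest mean in lists of other cell types. As edgeR called no gene, the first part was applied to the DESeq2 calls. One gene of the fixed set is not reported here.

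The tests were tried on simulated counts over the 12199 genes that edgeR tested, with the means and library sizes of these libraries. The spread of each gene was drawn from edgeR's own estimates, a setting that may favour edgeR. Of 50 genes per size, edgeR recovered 26 at a log2 change of 4, 19 at −4, 1 at 2 and 3 at −2, and DESeq2 recovered 33, 32, 5 and 10. Gene positions came from GENCODE vM21 on GRCm38. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.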

Results

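RNA was measured in innate lymphoid cell precursors (ILCPs), the bone marrow cells that give rise to innate lymphoid cells, sorted from Rag1-cre;ET-2 mice on a C57BL/6 background. ILCPs that expressed the ET-2 transgene were recognised by GFP and set against GFP− ILCPs of the same marrow. ET-2 is known, as background, as a fusion of the activation domains of the E protein E47 with the DNA-binding region of TAL1, made to raise E protein activity. There were 3 libraries of GFP+ ILCPs and 3 of GFP− ILCPs. Each replicate was a pool of several mice, and both fractions of a replicate came from that pool.

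The GFP+ libraries held 12760141, 15042354 and 10432461 estimated counts in replicates 1, 2 and 3, and the GFP− libraries held 11680512, 19038554 and 14584577. Of 16383 genes analysed, 14758, 12576 and 11240 were above 0 in GFP+ replicates 1, 2 and 3. The GFP− replicates had 15016, 14537 and 13786 genes above 0. GFP+ replicate 3 also gave 8.71% of its counts to ribosomal protein genes and 2.98% to immunoglobulin genes, against at most 3.40% and 0.136% in the other libraries. Correlations of log2 expression across genes were 0.672 to 0.891 within groups and 0.658 to 0.891 between groups.

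**Figure D1:**
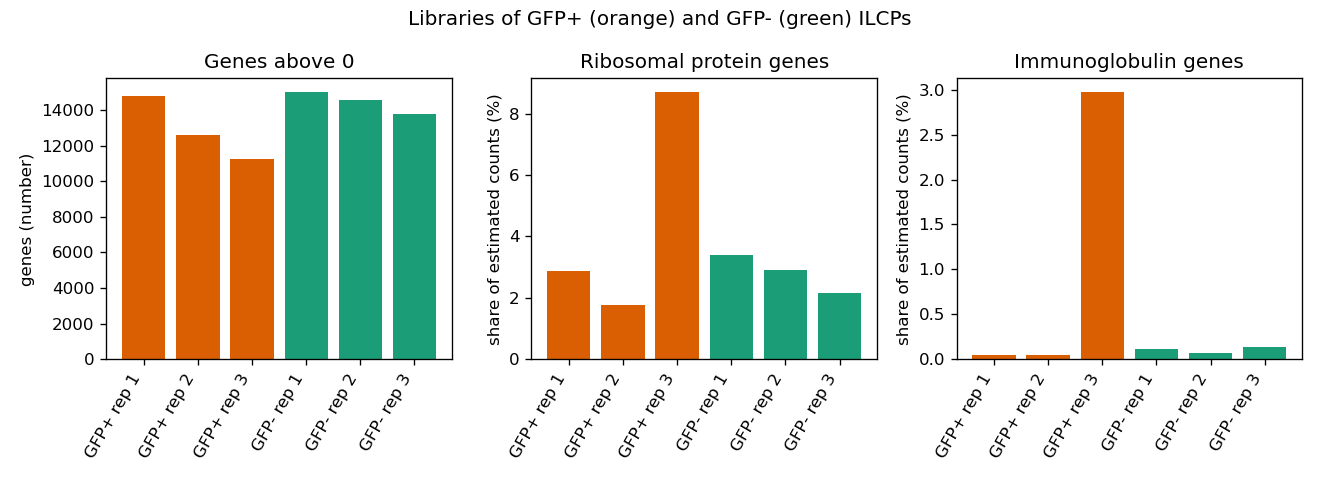
Genes above 0 (left, number), the share of estimated counts in ribosomal protein genes (middle, %) and in immunoglobulin genes (right, %) in each library, with 1 bar per library, GFP+ in orange and GFP− in green. GFP+ replicate 3 has the fewest genes above 0, at 11240, and the highest ribosomal protein share, at 8.71%.

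The comparison asked which genes differ between GFP+ and GFP− ILCPs. No library came from mice with Rag1-cre and without ET-2, so a history of Cre driven by Rag1 and the ET-2 transgene cannot be told apart. Ly6c1, a surface protein of the Ly6 family, stood at 128 ± 98.2 CPM (counts scaled to the library size; SD, n = 3) in GFP+ ILCPs and at 2.22 ± 1.31 CPM (SD, n = 3) in GFP− ILCPs, and was higher in 3 of 3 pairs. Epas1, which encodes the hypoxia-inducible factor HIF-2α, stood at 270 ± 210 CPM in GFP+ and 21.1 ± 13.8 CPM in GFP− ILCPs (SD, n = 3 each). Gzma, the cytotoxic granule protease granzyme A, and Rag1, a subunit of the V(D)J recombinase, had no counts in any GFP+ library. In GFP− ILCPs they stood at 6.84 ± 1.52 and 3.47 ± 1.36 CPM (SD, n = 3). edgeR's quasi-likelihood test called none of these genes over all genes.

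edgeR called 0 of 12199 genes at an adjusted p under 0.05, and its smallest value with Benjamini-Hochberg adjustment was 0.998. At an unadjusted p under 0.05 there were 394 genes, 216 higher and 178 lower, where 610 would be expected by chance. With the replicate block edgeR again called 0 genes, with 209 at an unadjusted p under 0.05. DESeq2, run on all 16383 genes without edgeR's filter, called 60 genes, 15 higher and 45 lower in GFP+ ILCPs, and 153 with the block. The authors' deposited table lists 98 genes with an adjusted p under 0.05, 35 higher and 63 lower, and all 60 DESeq2 calls are among them. Of the 98, 35 had over 80% of their summed CPM in 1 library, 16 of them called higher and 19 lower. edgeR's filter left 41 of these 98 untested in its main fit. In 10 draws of counts simulated from these libraries with no changed gene, DESeq2 called 34 to 54 of 12199 genes and edgeR 0 to 1, a check added after the calls were seen. The simulation held only the genes that edgeR tested and used edgeR's estimates of spread. DESeq2's 60 calls came from all 16383 genes, so 60 cannot be set against that range. Its calls among the genes that edgeR tested were fewer and did not exceed the highest count of that range, 54. Their adjusted p came from the fit of all genes. The fit with the replicate block was not simulated. In a further draw that also held changed genes, DESeq2 called 56 of the 11959 unchanged genes and edgeR 4. The common biological coefficient of variation was 0.922.

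Since edgeR called no gene, the genes named next are those that the rule for large changes takes from the DESeq2 calls, a step chosen after the values were seen. They are 11 genes called higher and 12 of the 33 called lower. edgeR's filter had left Stc2, Sp6, Gcg, Masp2, Fcer1a, Il12a, L1td1 and Maged2 out of its main fit, so there they were untested. The GFP+ libraries with the fewest genes above 0 were replicates 2 and 3, and of the 63 genes lower in the authors' deposited table, 47 had 0 counts in both. As these genes were called for low GFP+ values, this count alone does not show a source of the calls. DESeq2 calls ranged from 27 without GFP− replicate 2 to 682 without GFP+ replicate 1. They numbered 112 and 105 without GFP+ replicates 2 and 3, 30 without GFP− replicate 3 and 264 without replicate 1 of both groups. On genes above 0 in all 6 libraries DESeq2 called 10, all among the 60, while 48 of the 60 had no adjusted p in that setting.

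Among the genes called higher, Ly6c1 had a DESeq2 log2 fold change of 5.91 ± 0.94 (SE; DESeq2 adjusted p = 2.67e-06). It lies on chromosome 15 at 75044018 to 75048830, minus strand, in GRCm38 (GENCODE vM21), and has close relatives in the Ly6 family whose reads can be shared. Its relative Ly6c2 stood at 84.4, 1.25 and 757 CPM in GFP+ replicates 1, 2 and 3 against 85.6, 27.9 and 4.98 CPM in GFP− replicates. How reads were split between Ly6c1 and Ly6c2 was not tested, so the size of the Ly6c1 change may depend on it. Epas1, on chromosome 17 at 86753700 to 86833410, plus strand, had a log2 fold change of 3.76 ± 1.01 (SE; DESeq2 adjusted p = 0.0484). Its GFP+ values were 690, 3690 and 3857 counts against 495, 153 and 279. DESeq2 did not call Epas1 without GFP+ replicates 2 or 3 (adjusted p of 0.0835 and 0.12) or without GFP− replicates 1, 2 or 3 (0.0569, 0.342 and 0.217), within a range of 0.000542 to 0.342 over the alternatives. The splicing regulator Rbfox2 stood at 28.1 ± 21.8 against 1.02 ± 0.724 CPM (DESeq2 adjusted p = 0.00469, and 0.0758 and 0.0692 without replicates 2 and 3 of both groups, range 0.000226 to 0.0758), and the Mediator subunit Med18 at 90.5 ± 101 against 3.97 ± 1.82 CPM (SD, n = 3). Ica1 stood at 42.9 ± 62.7 against 0.635 ± 0.816 CPM, with 1388 of its counts in GFP+ replicate 2, without which DESeq2 did not call it (adjusted p = 0.496, range 1.17e-05 to 0.799 over the alternatives). Edaradd stood at 54.8 ± 37.9 against 7.24 ± 2.13 CPM (SD, n = 3). The iron exporter Slc40a1 and the macrophage receptor Adgre4 stood at 24.9 ± 28.02 and 8.05 ± 5.78 CPM against 1.79 ± 0.553 and 0.323 ± 0.261 CPM (SD, n = 3). Acyp2 stood at 7.80 ± 3.86 against 0.568 ± 0.456 CPM, and the transcription factor Sp6 at 9.05 ± 11.6 against 0.115 ± 0.143 CPM (SD, n = 3). The secreted glycoprotein Stc2 had 402, 4 and 40 counts in GFP+ libraries and 0 in the GFP− libraries, at least 166-fold higher against a floor of 3 counts over the group. Without GFP+ replicate 1 the bound for Stc2 was 41.5-fold, and without replicate 1 of both groups DESeq2 did not call it (adjusted p = 0.146, range 1.95e-05 to 0.146). Other calls of DESeq2 were lost without 1 library while the genes stayed higher. Without GFP+ replicate 3 the log2 fold changes of Sp6, Slc40a1, Acyp2 and Adgre4 went from 6.32, 3.91, 3.83 and 4.76 to 4.32, 2.33, 3.39 and 3.97 (DESeq2 adjusted p of 0.442, 0.211, 0.211 and 0.11). Slc40a1 stood at 57.2 CPM in that library and at 9.39 and 8.05 CPM in GFP+ replicates 1 and 2, and Adgre4 at 14.5 against 6.22 and 3.40 CPM, with at most 0.62 CPM of Adgre4 in a GFP− library. Without GFP+ replicate 2 those of Med18, Acyp2 and Edaradd went from 4.56, 3.83 and 2.97 to 3.20, 3.85 and 2.26 (DESeq2 adjusted p of 0.11, 0.113 and 0.114). DESeq2 gave Sp6, Ica1, Adgre4, Slc40a1, Acyp2 and Edaradd adjusted p of 0.108, 0.189, 0.0921, 0.1, 0.27 and 0.135 without GFP− replicate 1, and 0.0581, 0.0829, 0.127, 0.29, 0.0613 and 0.352 without GFP− replicate 2, where Med18 had 0.0996. Without GFP− replicate 3 it gave Sp6, Med18, Slc40a1, Acyp2 and Edaradd 0.0865, 0.119, 0.173, 0.169 and 0.123. Over the alternatives the DESeq2 adjusted p ranged from 0.00163 to 0.637 for Sp6, 0.00484 to 0.127 for Adgre4, 1.65e-05 to 0.378 for Med18, 0.00417 to 0.502 for Slc40a1, 0.0101 to 0.443 for Acyp2 and 0.0041 to 0.696 for Edaradd. With the replicate block, DESeq2 no longer called Slc40a1, Acyp2 and Edaradd, with adjusted p of 0.0677, 0.0991 and 0.0755.

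Of the 12 genes named as lower, 11 had 0 counts in every GFP+ library. The naming rule ranks by fold change, which puts such genes first nearly by choice. Of the 63 genes lower in the authors' deposited table, 30 had 0 counts in every GFP+ library. Gzma, on chromosome 13 at 113093825 to 113100981, minus strand, had 118, 114 and 90 counts in GFP− replicates 1, 2 and 3. It was at least 82.5-fold lower against a floor of 3 counts over the group (DESeq2 adjusted p = 0.000158). Rfc1, the large subunit of the clamp loader of DNA replication, had 183, 359 and 25 counts in the GFP− libraries and was at least 126-fold lower (DESeq2 adjusted p = 0.000176). Fcer1a, the IgE receptor subunit of mast cells and basophils, had 38, 12 and 249 counts in the GFP− libraries and was at least 90.9-fold lower. Without GFP− replicate 3 the bound for Fcer1a was 19.4-fold and DESeq2 did not call it (adjusted p = 0.802, range 0.00387 to 0.802). Il12a, a cytokine subunit, had 1, 58 and 168 counts and was at least 63.6-fold lower. Without GFP− replicate 3 its bound was 16.5-fold, and DESeq2 gave Il12a adjusted p of 1, 0.189 and 0.0546 without GFP− replicate 3, GFP− replicate 2 and GFP+ replicate 2 (range 0.0148 to 1). The others at 0 were Gcg, Masp2, Enthd1, L1td1, Maged2, Rsph10b and Rag1. Baiap2l1 had 1 count in GFP+ replicate 1 and 26, 74 and 245 in the GFP− libraries. Il12a, Rsph10b and Rag1 were not called by DESeq2 with the replicate block, at adjusted p of 0.083, 0.0964 and 0.055. Without GFP− replicate 1 the DESeq2 adjusted p of Gcg, Masp2, L1td1, Maged2 and Rsph10b was 0.0509, 0.0772, 0.0649, 0.1 and 0.0882, and without GFP− replicate 2 that of Enthd1 was 0.131. Without GFP− replicate 3 that of Gcg, Masp2, Enthd1, L1td1, Baiap2l1 and Rsph10b was 0.153, 0.151, 0.156, 1, 0.328 and 0.107, and without GFP+ replicate 2 that of Rsph10b was 0.0512. Over the alternatives the DESeq2 adjusted p ranged from 1.36e-05 to 0.153 for Gcg, 0.000268 to 0.151 for Masp2, 0.00297 to 0.156 for Enthd1, 0.0116 to 1 for L1td1, 0.00951 to 0.1 for Maged2, 0.00234 to 0.328 for Baiap2l1 and 0.0225 to 0.107 for Rsph10b. Of the 23 genes named, DESeq2 no longer called 7 and 5 without GFP+ replicates 2 and 3, and 13 and 15 without GFP− replicates 1 and 3. Without GFP− replicate 2 it kept 10, gave 11 an adjusted p of at least 0.05 and left the others without an adjusted p. Ly6c1, Gzma and Rfc1 stayed under 0.05 by DESeq2 in every alternative that tested them, with highest adjusted p of 0.000609, 0.0235 and 0.0361.

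**Figure D2:**
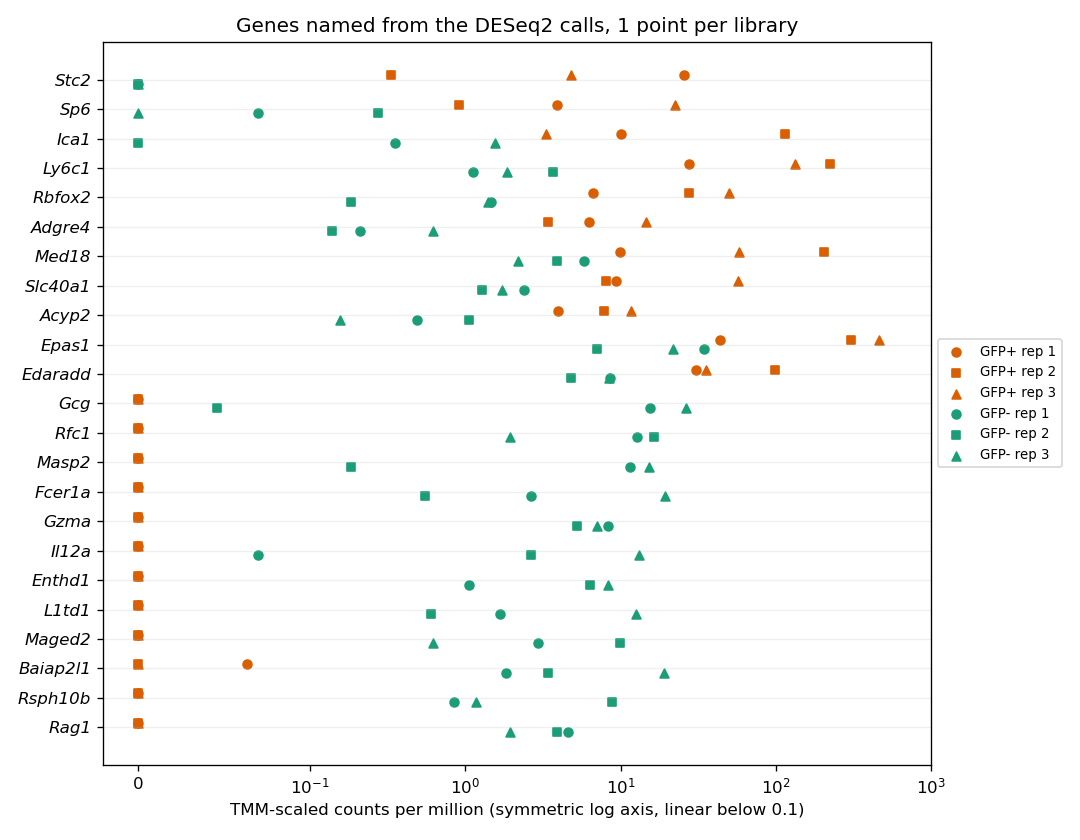
CPM (horizontal axis, symmetric log scale, linear below 0.1) of the genes named from the DESeq2 calls, with 1 point per library, GFP+ in orange and GFP− in green, and the shape giving the replicate. Ly6c1 lies higher in each GFP+ library than in any GFP− library, and Gzma and Rag1 lie at 0 in the GFP+ libraries.

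Rag1, whose regulatory sequence drives Cre in these mice, lies on chromosome 2 at 101638282 to 101649501, minus strand. Its 65, 85 and 25 counts in GFP− replicates 1, 2 and 3 stood against 0 in each GFP+ library, at least 41.9-fold lower against a floor of 3 counts over the group (DESeq2 adjusted p = 0.00684). That adjusted p ranged from 0.00509 to 0.276 over the alternatives, and was 0.27, 0.26 and 0.0598 without GFP− replicates 1, 2 and 3. Leaving out replicate 1 or 2 of both groups gave 0.16 and 0.276. Of the 6 recombination genes tested by edgeR, 3 were higher and 3 lower, 0 passed over all genes and 1, Rag1, passed when adjusted over the list alone. The median of these genes was 0.037 and their mean −1.38, the direction of the camera test (adjusted p = 0.372). Rag2, the partner of Rag1, stood at 47.9 ± 75.9 CPM in GFP+ and 22.6 ± 6.98 CPM in GFP− ILCPs (SD, n = 3).

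None of the E protein and inhibitor genes tested passed edgeR's test. Tcf3, which encodes E2A, stood at 92.5 ± 23.5 against 122 ± 9.87 CPM (SD, n = 3), with a log2 fold change of −0.40 ± 0.49 (SE). Tcf12 (HEB) and Tcf4 (E2-2) had log2 fold changes of −0.53 ± 0.53 and −0.77 ± 0.62 (SE), and Tcf12 was lower in 3 of 3 pairs. Id2, the inhibitor of E proteins that marks ILC precursors, stood at 312 ± 189 against 238 ± 37.8 CPM, and its log2 fold change of 0.39 became −0.21 without GFP+ replicate 3. Tal1 had 45.98 CPM in GFP− replicate 1 and at most 3.43 CPM elsewhere, and Id3 did not exceed 0.21 CPM in any library. Since the counts are per gene, they do not separate transgene RNA from Tcf3 or Tal1 RNA. Of 10 genes of the E and Id protein list tested, 4 were higher and 6 lower and 0 passed, with a median and mean log2 fold change below 0 while camera gave the direction as up (adjusted p = 0.939).

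The surface molecules of the sort gave 6 genes higher and 3 lower of 9, and 0 passed. Il7r stood at 2063 ± 696 against 1914 ± 685 CPM, Itga4 at 3769 ± 2693 against 3940 ± 2216 CPM, Itgb7 at 196 ± 118 against 118 ± 26.1 CPM and Thy1 at 346 ± 153 against 301 ± 114 CPM (SD, n = 3). Il2ra, which encodes CD25, the marker sorted against, stood at 151, 396 and 2032 CPM in GFP+ replicates 1, 2 and 3 and at 177, 324 and 340 CPM in GFP− replicates. Flt3 stood at 1.43 ± 1.31 against 2.01 ± 0.572 CPM (SD, n = 3).

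Genes of type 2 innate lymphoid cells (ILC2) were higher in GFP+ ILCPs as a list, in which 18 of 28 members were higher and 10 lower, with a median log2 fold change of 0.99 (camera adjusted p = 0.0125). The call was lost by camera at adjusted p = 0.758 with an estimated correlation. No single member passed edgeR over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05, all higher. Il1rl1, the IL-33 receptor, stood at 1421 ± 1230 against 361 ± 62.9 CPM (SD, n = 3) and was higher in 3 of 3 pairs. The highest of its values, 2833 CPM, came from GFP+ replicate 3. Gata3 and Rora, regulators of the lineage, stood at 667 ± 338 against 678 ± 310 CPM and at 1636 ± 904 against 2349 ± 422 CPM (SD, n = 3). The median ILC2 gene differed by −0.046, 0.14 and 1.42 log2 units in pairs 1, 2 and 3. Without GFP+ replicate 3 the camera adjusted p of the ILC2 list was 0.639, within a range of 0.000237 to 0.992 over the alternatives.

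Natural killer and ILC1 genes had 10 members higher and 18 lower of 28, with a median log2 fold change of −0.40, and missed the threshold (camera adjusted p = 0.0606). With the replicate block camera gave an adjusted p of 0.0359, and 0.851 with an estimated correlation. It was 0.0405, 0.0173 and 0.0119 without GFP+ replicate 1, GFP+ replicate 2 and GFP− replicate 2, within a range of 0.0036 to 0.992. The median gene of this list differed by −0.21, −0.043 and −3.84 log2 units in pairs 1, 2 and 3. Eomes stood at 9.58, 28.3 and 0 CPM in GFP+ replicates 1, 2 and 3 against 27.5, 31.4 and 116 CPM, and Tbx21 at 12.1, 0 and 0 CPM against 6.52, 4.73 and 17.7 CPM. DESeq2 gave Tbx21 an adjusted p of 0.997, and of 0.0283 with the replicate block, and edgeR did not call it (adjusted p of 0.43 to 1 over its alternatives). ILC3 genes had 11 of 19 members higher and 0 past the test. The ILC progenitor regulators had 8 of 15 higher and 0 past the test. Among them Tcf7 stood at 1718 ± 1757 against 1891 ± 400.2 CPM, and Bcl11b at 391 ± 75.1 against 304 ± 52.7 CPM (SD, n = 3).

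T lineage genes had 15 of 26 members higher and 11 lower, and Notch pathway genes 6 of 9 higher and 3 lower, and 0 of either passed. Ptcra, the pre-T cell receptor chain, stood at 4.34 ± 2.81 against 1.48 ± 0.805 CPM (SD, n = 3) and was higher in 3 of 3 pairs. Cd3e stood at 163, 79.4 and 0 CPM in GFP+ replicates 1, 2 and 3 against 60.4, 32.5 and 7.31 CPM. Tcrg-C1 stood at 2489 ± 1812 against 1037 ± 429 CPM (SD, n = 3). Cytokine receptors and signalling genes had 15 of 28 higher, trafficking receptors 15 of 24, interferon response genes 15 of 22 and immediate early and heat shock genes 17 of 25, with 0 past the test in each. Cell cycle inhibitors had 7 of 11 higher and apoptosis regulators 9 of 16, also with 0 past the test. The apoptosis list had a median and mean above 0 while camera gave its direction as down. Lists whose result is not given separately had camera adjusted p between 0.0688 and 0.895. Scaling by total counts moved the median of all tested genes by −0.16 log2 units, and turned the medians of the recombination, ILC progenitor, sort surface, cytokine receptor and stromal lists to −0.13, −0.21, −0.044, −0.14 and −0.22. Adjusted over the list alone, edgeR passed 0 members of every list but the recombination genes.

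Mitosis genes were lower in GFP+ ILCPs as a list, with 16 of 20 members lower and a median log2 fold change of −0.61 (camera adjusted p = 0.0125). The adjusted p was 0.758 with an estimated correlation, again by camera. The median mitosis gene differed by −0.29, −0.20 and −2.32 log2 units in pairs 1, 2 and 3, and camera gave adjusted p of 0.3 without GFP+ replicate 3, 0.113 without GFP+ replicate 1 and 0.0671 without GFP− replicate 2. Of 21 DNA replication genes, 14 were lower and 7 higher (camera adjusted p = 0.0606, and 0.0311 and 0.0181 without GFP+ replicate 2 and GFP− replicate 3, within a range of 0.0181 to 0.992). With an estimated correlation camera gave the DNA replication list an adjusted p of 0.758, and 0.851 with the replicate block as well.

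Ribosomal protein genes were higher as a list, with 81 of 87 members higher and a median log2 fold change of 1.10 (camera adjusted p = 1.59e-10, and adjusted p = 0.758 with an estimated correlation). They differed by −0.24, −0.42 and 2.59 log2 units in pairs 1, 2 and 3, and without GFP+ replicate 3 the direction was reversed (camera adjusted p = 0.582). The 13 mitochondrially encoded genes were all higher, with a median of 0.61 (camera adjusted p = 0.0155, and adjusted p = 0.759 with an estimated correlation). Their pairs differed by −0.26, 3.14 and −1.05 log2 units, and camera gave adjusted p of 0.937 and 0.3 without GFP+ replicates 2 and 3, and 0.544 and 0.319 without GFP− replicates 1 and 2. Over the alternatives the adjusted p ranged up to 0.992 for the mitosis, ribosomal protein and mitochondrially encoded lists. The 4 lists past the camera threshold became 0 without GFP+ replicate 3 and 8 without GFP+ replicate 2.

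**Figure D3:**
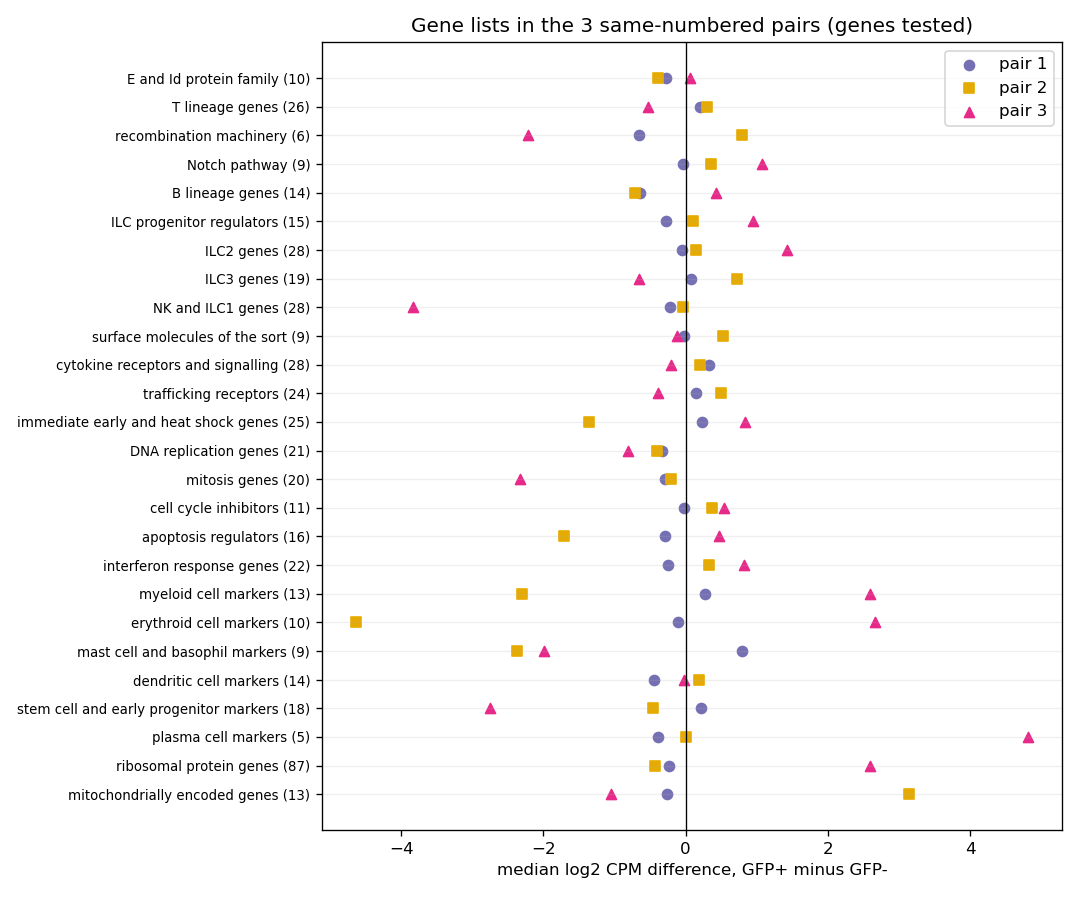
Median log2 CPM difference between GFP+ and GFP− ILCPs (horizontal axis) of each gene list in the 3 pairs, with 1 point per pair and the number of genes tested in brackets. The NK and ILC1 list lies at −3.84 in pair 3, and the ribosomal protein list at 2.59, while both lie within 0.5 of 0 in pairs 1 and 2.

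Some markers of other cells stood out in single libraries. Of 14 B lineage genes 7 were higher and 7 lower, and of 5 plasma cell markers 4 were higher, with 0 past the test. Igkc stood at 13677 CPM in GFP+ replicate 3 against at most 212 CPM in the other libraries, and Ighm at 9705 CPM against at most 1320 CPM. DESeq2 gave Igkc an adjusted p of 0.0153 with the replicate block and left it empty without the block. In the authors' deposited table its adjusted p is 0.221, and edgeR did not call it. The plasma cell genes Igha and Jchain stood at 3002 and 802 CPM in GFP+ replicate 3. Of 13 myeloid markers 9 were higher. Lyz2 stood at 714, 24.8 and 819 CPM in GFP+ replicates 1, 2 and 3 and at 250, 144 and 99.96 CPM in GFP− replicates, and Ly6c2 at 84.4, 1.25 and 757 CPM against 85.6, 27.9 and 4.98 CPM. Of 10 erythroid markers 7 were higher, with Car2 at 75.5 ± 45.0 against 20.8 ± 16.3 CPM and Tfrc at 42.1 ± 10.5 against 80.2 ± 24.4 CPM (SD, n = 3).

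Of 9 mast cell and basophil markers 7 were lower. Cpa3 stood at 837 ± 453 against 269 ± 198 CPM (SD, n = 3), higher in 3 of 3 pairs, and Mcpt8 at 27.2 ± 35.3 against 127 ± 186 CPM. Of 14 dendritic cell markers 7 were higher and 7 lower, with Ccr9 at 1119 ± 624 against 465 ± 148 CPM and Cd74 at 716 ± 639 against 377 ± 73.9 CPM (SD, n = 3). Of 18 stem cell and early progenitor markers 14 were lower (camera adjusted p = 0.0606, 0.0359 with the replicate block and 0.0201 without GFP+ replicate 1, within a range of 0.0201 to 0.992). With the block and an estimated correlation camera gave an adjusted p of 0.851. Satb1 and Hlf of that list stood at 754 ± 185 against 525 ± 115 CPM and at 392 ± 83.3 against 359 ± 78.5 CPM (SD, n = 3). Megakaryocyte markers and stromal and endothelial markers had 4 members tested each, 2 higher and 2 lower in both. Itgb3 and Itga2b stood at 846 ± 269 against 529 ± 224 CPM and 6.87 ± 11.6 against 12.7 ± 3.25 CPM (SD, n = 3). Pecam1 and Pdgfrb stood at 258 ± 130 against 293 ± 83.5 CPM and 15.6 ± 17.2 against 13.2 ± 4.31 CPM (SD, n = 3). None of these members passed edgeR over all genes.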

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

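The DESeq2 alternatives, limma, the lists without single libraries and the alternatives of fry without direction were chosen after seeing the data. edgeR called 0 genes under the replicate block, both other scalings, both other filters, both other thresholds and each replicate or library left out, with 209 genes at an unadjusted p under 0.05 with the replicate block and 1367 without GFP+ replicate 1. DESeq2 called 60, limma with sample weights 0, and limma with the replicate block 10. The DESeq2 calls became 153 with the replicate block, of which 38 were among the 60, and 10 on genes above 0 in all 6 libraries, where fewer genes were tested. They ranged from 27 to 682 with replicates or libraries left out. With its filter on outlying counts (Cook's distance) off, DESeq2 called 79 genes, the 60 included and all among the authors' 98. By default, 19 of those 98 had no adjusted p. For other differences the cause was not tested. Scaling by the total gave Il7r −0.11 and Thy1 −0.044. Gata3 was 0.051 with DESeq2 scaling and 0.050 by DESeq2, and Cd3e −0.10 with the replicate block.

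By camera, 4 lists passed, 6 with the replicate block, 0 with an estimated correlation, 0 with both, and 0 by fry with a direction, and the count ranged from 0 to 8 with libraries left out. Adjusted p with an estimated correlation was 0.758 for the ILC2, mitosis and ribosomal protein genes and 0.759 for mitochondrially encoded genes, and 0.851 for all 4 with the replicate block as well. Fry gave 0.992 for those 4. It also gave 0.992, with the direction reversed, for E and Id protein family, T lineage genes, B lineage genes, ILC progenitor regulators, ILC3 genes, immediate early and heat shock genes, cell cycle inhibitors and myeloid cell markers. Rag1 is a member of both the recombination and B lineage lists, and the only member of each that DESeq2 called. Fry without direction passed the recombination (adjusted p = 0.00226, range 0.00321 to 0.755 over its alternatives) and B lineage lists (0.00903, range 0.00421 to 0.973). Those were 0.052 and 0.164 without GFP+ replicate 2, 0.0984 and 0.57 without GFP− replicate 1 and 0.187 and 0.973 without GFP− replicate 2 by fry. Beyond the lists that passed camera, the replicate block changed only the calls of the NK and ILC1 and the stem cell lists, among lists tested by camera. Of the 23 genes named from the DESeq2 calls, 6 lost the call with the block, as given in the results, and the block changed no other call of these; for Cdk4, Pou2f2, Tbx21 and Igkc its value stands beside the result.

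With replicates or libraries left out, camera's adjusted p ranged from 0.000237 to 0.75 for ILC2 genes, 1.54e-05 to 0.3 for mitosis genes, 1.53e-22 to 0.582 for ribosomal protein genes and 8.17e-10 to 0.937 for mitochondrially encoded genes. Ribosomal protein genes were lower without replicate 3 (adjusted p = 0.0105 by camera), and mitochondrially encoded genes were lower without replicate 2 (0.51). Ranges of lists whose direction was reversed in some of these fits were 0.57 to 0.892 for E and Id protein family, 0.154 to 0.985 for T lineage genes, 0.361 to 0.887 for B lineage genes and 0.342 to 0.985 for ILC progenitor regulators. They were 0.187 to 0.847 for ILC3 genes, 2e-04 to 0.994 for immediate early and heat shock genes, 0.565 to 0.953 for cell cycle inhibitors and 0.3 to 0.947 for apoptosis regulators. They were 0.00297 to 0.947 for myeloid, 0.0342 to 0.974 for erythroid, 0.235 to 0.927 for mast cell and basophil, 0.454 to 0.973 for dendritic and 0.0885 to 0.994 for plasma cell markers. Without GFP+ replicate 2 the immediate early, myeloid and erythroid lists passed camera as higher (2e-04, 0.00297 and 0.0342), and without replicate 1 of both groups the interferon list did (0.0414). With an estimated correlation camera gave these 4 lists 0.919, 0.949, 0.919 and 0.758 on all 6 libraries, and that correlation was not run with libraries left out.

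The log2 fold changes of fixed genes that changed sign with a replicate or library left out ranged from −7.91 to 1.47 for Tal1, −0.30 to 0.75 for Id2, −0.12 to 0.43 for Il7r, −0.98 to 0.83 for Itga4, −0.054 to 1.08 for Itgb7, −0.44 to 0.76 for Thy1 and −0.033 to 2.18 for Il2ra. They ranged from −1.42 to 0.27 for Flt3, −0.70 to 0.61 for Gata3, −1.39 to 0.46 for Tcf7 and −10.25 to 0.10 for Tbx21. Of 21 fixed genes tested and reported, 12 changed sign under some alternative. Alternatives for normalized values, such as other pseudocounts, were not run because the values are counts. The depth limits what can be said of genes near the floor. Total counts did not follow the genes at 0 in every library. GFP+ replicate 2 had 3807 genes at 0 from 15042354 counts, and GFP− replicate 1 had 1367 from 11680512. GFP+ replicate 3 had the fewest counts, 10432461, and the most genes at 0, 5143.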

Other observations

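The tests of macrophage RNA, of the ILC2 list by pair, of the fall with transcript length and of the ILC2-type cells and the count of genes like Rag1 were chosen after their results or related values were seen. Cdk4, Mlkl, F2r, Pou2f2, Il1rap, Il20ra and Ighg2b were chosen after their values were seen. edgeR called none of them, and its filter left Ighg2b untested in the main fit. The first 4 were above 0 in all 6 libraries. Cdk4, a kinase of G1 progression, stood at 23.4 ± 7.005 CPM in GFP+ and 125 ± 15.5 CPM in GFP− ILCPs (SD, n = 3) and was lower in 3 of 3 pairs. Its DESeq2 log2 fold change was −2.35 ± 0.61 (SE; DESeq2 adjusted p = 0.0346, and 0.0769 with the replicate block). Mlkl, the effector of necroptosis, stood at 1.10 ± 0.647 against 15.0 ± 4.07 CPM (SD, n = 3; DESeq2 adjusted p = 0.00601, and 0.0284 with the block). F2r, the thrombin receptor, stood at 349 ± 118 against 73.9 ± 34.4 CPM and was higher in 3 of 3 pairs (DESeq2 adjusted p = 0.117, and 0.0991 with the block). Pou2f2, the transcription factor OCT2, stood at 278 ± 231 against 34.4 ± 9.58 CPM (SD, n = 3; DESeq2 adjusted p = 0.0679, and 0.0481 with the block). The authors' deposited table calls all 4, with adjusted p of 0.00473, 0.000967, 0.0333 and 0.0194.

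Among other receptors, Il1rap, the shared subunit of the IL-1 and IL-33 receptors, stood at 74.3 ± 27.7 against 15.6 ± 2.67 CPM (SD, n = 3), higher in 3 of 3 pairs (DESeq2 adjusted p = 0.0697, and 0.124 with the block). Il20ra stood at 0.369 ± 0.338 against 14.7 ± 6.30 CPM (SD, n = 3), lower in 3 of 3 pairs (DESeq2 adjusted p = 0.00103, and 0.00258 with the block). Ighg2b had 70098 counts in GFP+ replicate 3 and at most 38 elsewhere, and the authors' deposited table calls it with an adjusted p of 0.000723. Of 666 genes with a level like that of Rag1 in GFP− ILCPs and at least as even there, 5 (0.751%, exact 95% interval 0.244 to 1.74%) had 0 counts in all GFP+ libraries. The set was thus not matched to Rag1 on evenness. Rag1 itself is counted among the 666 and the 5.

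The first pattern is the set of genes called lower. In the held-out test, among 140 genes at 0 in GFP+ replicates 2 and 3 with at least 20 counts in each GFP− library, GFP+ replicate 1 lay under 0.1 of the GFP− mean in 18.6% (exact 95% interval 12.5 to 26%). GFP− replicates 1, 2 and 3, each held out against the other GFP− libraries and GFP+ replicate 1, gave 5.93, 20.6 and 34.9%. Their exact 95% intervals were 2.42 to 11.8%, 14.1 to 28.4% and 28.2 to 42.1%. GFP− replicate 1 thus lay below GFP+ replicate 1, and GFP− replicate 3, the highest, has the most genes at 0 among the GFP− libraries. The 3 libraries with the most genes at 0, GFP+ replicates 2 and 3 and GFP− replicate 3, shared 392 genes at 0 that the other 3 detected, against 123 for the GFP+ libraries, but the choice of these libraries by their genes at 0 nearly fixes a larger count, so on this value library complexity and the transgene cannot be told apart. The held-out test leaves the fewer genes detected in GFP+ replicates 2 and 3 as a candidate source of many of these calls, and an effect of ET-2 on single genes stays open.

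The second pattern is the set of genes called higher by DESeq2 or in the authors' deposited table, in which C1qc, Apoe, Fcna, Slc40a1 and Adgre4 are known from macrophages. The median of 17 other macrophage markers, 4 of them also in the myeloid list and 15 with a GFP− mean of at least 1 CPM, lay 2.07 log2 units above the GFP− mean in GFP+ replicate 1 (bootstrap 95% interval 0.84 to 3.24, 16 higher). It lay 1.68 above it in GFP+ replicate 3 (interval −1.42 to 3.29, 10 higher) and at −1.01 in GFP+ replicate 2 (interval −2.04 to −0.16, 4 higher), or −0.50 with the 5 called genes added (interval −1.33 to 0.13). Those 5 were taken from the genes called higher in these same data, so adding them raises the median by choice and decides nothing. Lyz2, the marker with the highest mean, stood at 714, 24.8 and 819 CPM in GFP+ replicates 1, 2 and 3, Cd163 at 17.7, 83.5 and 4.88 CPM and C1qb at 5.77, 29.8 and 46.5 CPM. Macrophage RNA may add to these calls in GFP+ replicate 1, although the sort would remove such cells. In replicate 2 most of the 17 markers were lower while Cd163 and C1qb were higher, and in replicate 3 the members go both ways, so it stays open in both.

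The third pattern is the higher ILC2 list. The median ILC2 gene differed by −0.046, 0.14 and 1.42 log2 units in pairs 1, 2 and 3 (bootstrap 95% intervals over genes −0.25 to 0.077, −0.32 to 1.05 and 0.29 to 2.40), and with 1 library per group in each pair, a transgene effect of similar size in every replicate and the spread between libraries cannot be told apart. Removing the trend with transcript length and level moved the median ribosomal protein gene in pair 3 from 2.59 to 2.27 and the median ILC2 gene from 1.42 to 1.41, a fall of 0.0042 (interval −0.51 to 0.25) where a fall of 0.92 was needed to reach 0.5, which argues against length as the whole source; a lower limit above 0.5, the bound set first, was not met before the correction either (0.29), so it could not decide. In pair 3 the NK and ILC1 list differed by −3.84 while Il2ra was 2.58 log2 units higher. In that pair 19 of the 28 ILC2 genes were higher, Gata3 among them at 945 against 328 CPM, while Rora was lower at 685 against 2726 CPM. More CD25-positive ILC2-type cells in GFP+ replicate 3 stay possible, although the sort excluded CD25. These values cannot decide it: Il2ra is itself a member of the ILC2 list, and GFP+ replicate 3 had 5143 genes at 0, which can lower the NK and ILC1 list whatever the cells. An effect of ET-2 seen in that pool alone stays open, and so does the low number of genes detected in that library.

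The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. edgeR gave 0 genes in the real split and 0 at most in the others, with all 10 as large, and 394 genes at an unadjusted p under 0.05 in the real split. DESeq2 gave 60 genes in the real split and 389 in the highest other, with 4 of 10 as large. That other split set GFP+ replicate 1 and GFP− replicates 1 and 2 against the 3 libraries with the most genes at 0, a structure of the samples that follows genes detected. Of the 4 splits that part all 3 replicate pairs, the real one included, the highest other gave 46 genes by DESeq2 and 7 lists by camera, and the remaining splits keep pairs together. With the block on the real split DESeq2 called 153. Camera gave 4 lists in the real split and 13 in the highest other, with 8 of 10 as large.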
